A study of Mus musculus with 8 samples.

How the data were processed

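Gene expression was measured by RNA sequencing in 8 libraries of mesenchymal cells sorted from mouse large intestine. The sorting gate, per the labels, kept cells negative for CD45, EpCAM and CD31, positive for gp38 (podoplanin), high for PDGFRα and negative for Ly6C. Total RNA was extracted with a column kit for small samples, full-length cDNA was made with a SMART-Seq HT kit, and libraries were built with Nextera XT, per the labels' protocols. SMART-Seq primes on poly(A) and does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart in these values.

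The authors deposited 1 table per library with a value in FPKM (fragments scaled by transcript length and by mapped fragments of the library) for each of 24346 gene symbols, per the file headers. The submitters' processing notes name TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18, Cuffdiff 2.2.1 and the build mm10, with no role or order. The annotation, the treatment of reads that map to several genes and any scaling between libraries are not given in the sources used here. FPKM are not counts, so no count-based test was used. Total FPKM per library ran from 513001 to 579004. The number of reads per library is unknown. Low FPKM values of a gene move in steps of what 1 read is worth, and the most frequent log2 ratio between genes under 0.5 FPKM in 2 libraries was used to estimate their relative depth. By this estimate the conditional knockout library was 1.26 times as deep as the control library, with 24% of 1842 low genes within 0.01 of that log2 ratio. The other libraries of the time comparison lay between 0.824 and 0.959 times the depth of the 0 h replicate 1 library, where only 7.6% to 9.5% of low genes sat at the step. Any scaling by the authors would enter these estimates.

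Groups were taken from the labels. The genotype comparison set 1 library from a floxed Cxcl12 control mouse line against 1 library from the same line carrying Foxl1-Cre. The time comparison set 3 libraries at 0 h against 3 libraries at 6 h of treatment with 1 mM GABA and 20 mM taurine. The labels do not say that the 3 replicates were separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. Tests were run only within a comparison, because the 2 sets of libraries may have been normalised separately. No 2 libraries held the same values: over all pairs, 2 genes at or above 1 FPKM had equal values.

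For the time comparison, log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, over the 10910 genes with a mean of at least 1 FPKM in the 6 libraries. Adjusted p-values are Benjamini-Hochberg values from this moderated limma test, and the threshold was 0.05. A log2 difference on this scale understates the change of genes near 1 FPKM. Before the data were examined, 38 gene lists were fixed, 30 of pathways and gene families and 8 of cell type markers, together with the tests and most alternatives. Of their 634 genes, 633 were listed in the tables. The 34 lists with at least 3 tested members were tested with limma camera at a preset correlation between genes of 0.01, two-sided. Camera with an estimated correlation and fry, a self-contained rotation test, were run beside it. Single genes of the fixed set were also tested with an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

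With 1 library per genotype, no test of the genotype comparison was possible. Differences are log2 ratios of FPKM + 1 over the 14949 genes with a mean of at least 1 FPKM in the 2 libraries. The median of each list was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, and a list stood apart below percentile 2.5 or above 97.5. This percentile describes these 2 libraries and is not a p-value.

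Genes named in the text followed a fixed rule. Named in both comparisons were Cxcl12, Cxcr4, Ackr3, Foxl1, Pdgfra, Pdpn, Ly6c1, Epcam, Ptprc and Pecam1. For the time comparison they were joined by the 10 largest rises and the 10 largest falls among genes past the threshold whose 3 values in 1 group all lay beyond the 3 of the other and whose higher group mean was at least 10 FPKM. For each list, up to 4 members with the smallest p were named where the list passed, and up to 2 elsewhere. For the genotype comparison the rule took the 10 largest rises and falls among genes with at least 10 FPKM in a library, and up to 4 members of each list that stood apart, in its direction. Predicted genes, ribosomal protein pseudogenes, microRNAs, snoRNAs and snRNAs were passed over. None was passed over in the time comparison, and 21 among rises and 29 among falls in the genotype comparison. Genes named outside this rule are marked as chosen after their values were seen.

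Each script was tested on simulated data. With 200 changed genes planted among 10910 in the design of the time comparison, limma called 48 of 100 genes planted at an absolute log2 change of 0.5 and 88 of 100 planted at 1, with 8 false calls. With no planted change it called 0 genes and 0 lists. Genes were simulated as independent, so this does not show how the list test behaves when members vary together. In the data the estimated correlation was, for example, 0.253 among interferon-stimulated genes. With the log2 ratios of the genotype comparison shuffled over its 14949 genes, 3 of 37 lists stood apart with no change present.

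Alternatives were a pseudocount of 0.1, no filter, stricter filters of 5 FPKM (time) and 10 FPKM (genotype), rescaling to a median ratio of 1, quantile normalisation, no intensity trend, library quality weights, a term for the replicate number, and leaving out each library of the time comparison in turn. GC corrections and a count without small RNA genes were added after the data had been seen. GC content came from GENCODE M21 transcripts, as the whole transcript and as its most GC-rich 100-nt window. The corrections fitted a loess curve with a span of 0.3 to each library. Gene positions are from GENCODE M21 on GRCm38, the assembly that mm10 names. Ratios and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.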

Results

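RNA sequencing data were collected from 8 libraries of mesenchymal cells sorted from the mouse large intestine, a fraction that the series describes by high expression of the transcription factor Foxl1. Foxl1-expressing mesenchymal cells lie directly under the gut epithelium, and Cxcl12, the chemokine that the series is about, signals through Cxcr4 and is scavenged by Ackr3. Untreated cells of a floxed Cxcl12 control and of a conditional knockout, in which Foxl1-Cre deletes the floxed Cxcl12 gene, gave 1 library each. Cells of C57BL/6 mice treated with the amino acids GABA (1 mM) and taurine (20 mM) gave 3 libraries at 0 h and 3 at 6 h. Between 14818 and 21006 of the 24346 listed genes had a value above 0. The number of reads behind the FPKM values is unknown, so no counting interval is given.

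The genotype comparison asks what the sorted cells express when Cxcl12 is deleted in Foxl1-expressing cells. Cxcl12 itself was lower in the conditional knockout library, at 739.7 FPKM against 1298 FPKM in the control library. This is 57% of the control value and a fall by 0.81 on the log2(FPKM + 1) scale. Cxcl12 lies on chromosome 6 from 117168535 to 117181367 (GRCm38, plus strand) and is protein-coding. Among 823 genes with at least 100 FPKM in the control library, its fall ranked 2, behind Pam (127.1 FPKM in the control, 57.1 FPKM in the knockout), an enzyme of peptide amidation that was chosen after its values were seen. Predicted genes, ribosomal protein pseudogenes, microRNAs, snoRNAs and snRNAs were left out of this ranking. The FPKM values cover the whole Cxcl12 gene, and which exon was floxed is not given in the sources used here, so transcripts without that exon would still count. The share of sorted cells with Cre activity is also unknown, so the remaining 57% does not measure how completely the gene was deleted. Foxl1, on chromosome 8 from 121127940 to 121130644, stood at 10.2 FPKM in the control and 11.6 FPKM in the knockout library. With 1 library per genotype no difference of this comparison has a replicate check.

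The fixed markers of epithelium were higher in the conditional knockout library. All 17 measured epithelial markers were higher there, 14 of them at least 2-fold, with a median log2 difference of 2.06 that lay at percentile 100 of random lists. Car1, a carbonic anhydrase of colonocytes, stood at 614 FPKM against 57.2 FPKM in the control. Guca2a, the precursor of the hormone guanylin, stood at 137.6 against 13.2 FPKM, Krt8 at 87.7 against 8.46 FPKM, Krt19 at 52.9 against 4.61 FPKM and Phgr1 at 46.8 against 0.604 FPKM. Epcam, a surface protein that the sorting gate excluded, stood at 14.6 against 4.18 FPKM. Cyp2c55 (82.2 against 8.37 FPKM) and Fabp2 (15.2 against 1.32 FPKM) were also among the 10 largest rises. The rest of the 10 were Snhg9, listed at 0 in the control and 35.7 FPKM in the knockout, and Ccl21a and Lgals6. In the genotype libraries 43 genes with a mean of at least 10 FPKM were listed at 0 in a library. Small RNA genes made up 41 of these, so a listed 0 may not mean absence and the rise of Snhg9 is uncertain. Ccl21a (18.2 against 0.00502 FPKM) and Lgals6 (12.8 against 0.507 FPKM) have near-identical paralogs among which reads may have been split, so their values are uncertain.

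The 10 largest falls held genes of diverse kinds. Dbp, a transcription factor of the circadian clock output, stood at 14.1 FPKM against 38.8 FPKM in the control. The secreted antimicrobial lectin Reg3b stood at 9.57 against 23.6 FPKM, the chitinase-like protein gene Chil1 at 3.75 against 13.2 FPKM, and Mptx1, a pentraxin gene, at 4.83 against 26.2 FPKM. Reg3b and Mptx1 are expressed in gut epithelium and lay opposite to the epithelial markers. Hotairm1, a noncoding RNA of the Hoxa cluster, stood at 3.07 against 11.5 FPKM. Scgb1b19 (2.13 against 16.0 FPKM), Defb40 (3.25 against 20.4 FPKM) and Tnp1 (1.49 against 10.3 FPKM) were also among them. Rprl1 was listed at 0 in the knockout library and at 19.2 FPKM in the control, and this 0 is as uncertain as that of Snhg9. The largest fall, Amd1 (0.1 against 24.6 FPKM), is uncertain because Amd2, a near-identical single-exon copy, was higher in the knockout library. The sum of Amd1 and Amd2 was 33.2 FPKM in the control and 30.8 FPKM in the knockout library.

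Of the 37 gene lists measured, 10 stood apart in the conditional knockout library, while 3 stood apart in shuffled data. The data were shuffled a single time, which also breaks the correlation between members of a list, so the 2 counts do not form a test. Beside the epithelial markers, 8 lists lay higher by small amounts. Genes of like expression leaned upward too: the random lists matched to these 8 had medians from 0.047 to 0.087. The counts of higher members below include this general lean. Immediate early genes had a median log2 difference of 0.23, with 23 of 24 members higher, among them Maff, Nr4a2, Fosl1 and Nr4a3. Cholesterol synthesis genes had a median of 0.25, with 19 of 20 members higher. Among them Hmgcs1 stood at 53.9 against 35.0 FPKM in the control, Idi1 at 36.0 against 23.5 FPKM and Sqle at 49.8 against 32.8 FPKM. All 25 collagens and matrix proteins were higher, with a median of 0.16, Vcan (25.9 against 18.2 FPKM), Col6a3, Lox and Fbn1 most of all. Matrix remodelling enzymes had a median of 0.24 and 13 of 17 higher, with the stromelysin Mmp10 at 51.5 against 26.3 FPKM, followed by Adamts4, Mmp3 and Plat. Growth factors had a median of 0.2 and 17 of 23 higher, with the EGF receptor ligand Areg at 15.6 against 9.05 FPKM and Igf1 at 36.7 against 24.8 FPKM, then Vegfc and Vegfa. The largest single difference in that list was a lower value, that of Fgf2 (2.3 against 5.77 FPKM), chosen after its values were seen. Its ratio of 0.3991 was also that of Nog and Gabbr2, both under 0.5 FPKM, so the fall of Fgf2 may rest on few reads. Taurine transport and metabolism genes had a median of 0.29 over 7 measured members, 5 of them higher, with Ggt7, Csad, Ado and Fmo1 furthest. Without the filter the median of all 11 members was 0.02 at percentile 49.1, and this list did not stand apart. Osmotic response genes had a median of 0.25 over 8 members, 7 of them higher, with Slc5a3, Nfat5, Hspa4l and Sgk1 furthest, and did not stand apart with a pseudocount of 0.1 (percentile 96.8). Epithelial markers were higher in the same library as each of these lists.

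Markers of 2 other cell types outside the sorting gate also stood apart, in opposite directions. Leukocyte markers had a median log2 difference of 0.31, with 13 of 16 higher, among them Adgre1 (3.44 against 1.24 FPKM), Coro1a and Cd3e. Ptprc, which encodes CD45, stood at 6.85 against 4.82 FPKM. Among the lists that stood apart, only the endothelial markers lay lower, with a median of -0.65 over 11 members, 7 of them lower and 4 higher. Egfl7 stood at 0.557 against 5.4 FPKM, Plvap at 11.8 against 22.5 FPKM, Emcn at 1.44 against 3.97 FPKM, Kdr at 1.78 against 4.57 FPKM, and Pecam1, which encodes CD31, at 2.75 against 4.86 FPKM. Among the 3 endothelial markers with a mean of at least 10 FPKM the median was 0.03, and the list no longer stood apart. Pdgfra (225.7 against 201.8 FPKM), Pdpn (91.7 against 96.1 FPKM) and Ackr3 (143 against 136.6 FPKM) were close in both libraries. Ly6c1 stood at 89.6 against 140.9 FPKM, although the gate was set to keep Ly6C-negative cells, and Cxcr4 at 1.68 against 2.6 FPKM.

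**Figure D1:**
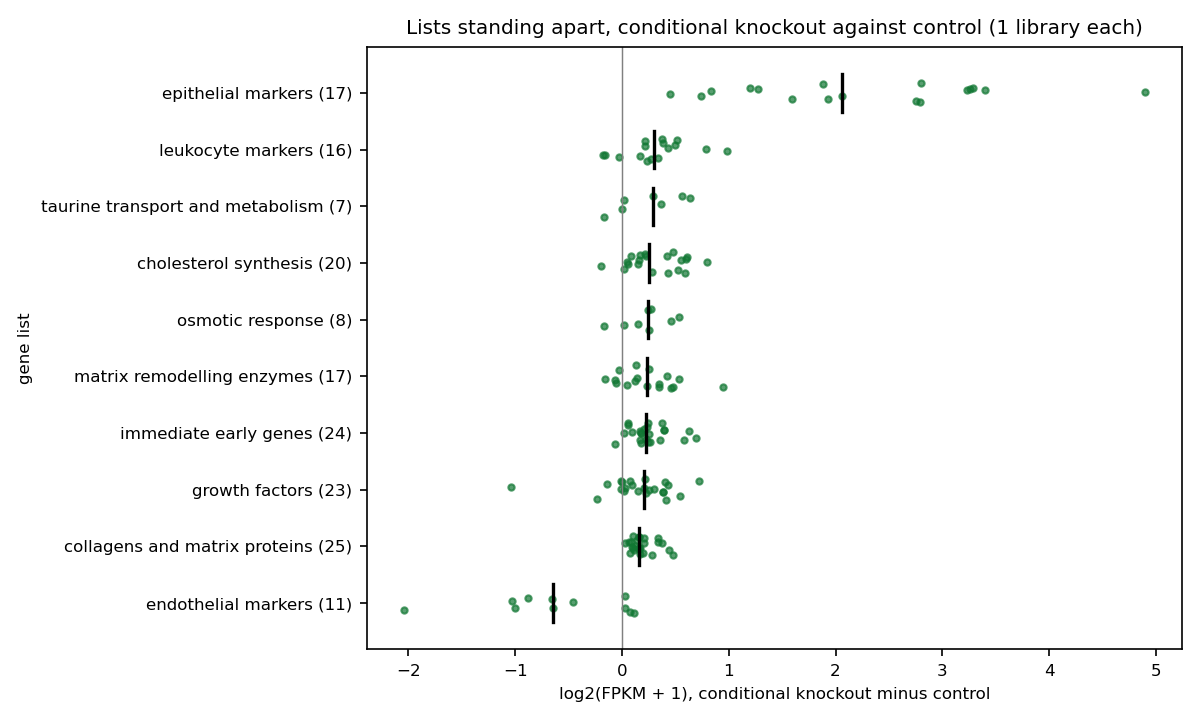
Difference in log2(FPKM + 1) between the conditional knockout and the control library (x axis) for each measured member (points) of the 10 lists that stood apart (y axis, members in brackets), with the median of each list as a black line; there is 1 library per genotype. The epithelial markers lie highest, at a median of 2.06, and the endothelial markers lowest, at a median of -0.65.

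In all, 204 of 14949 genes were at least 2-fold higher and 332 at least 2-fold lower in the conditional knockout library on the log2(FPKM + 1) scale. Small RNA genes made up 21 of the former and 27 of the latter. Among genes with a mean of at least 10 FPKM the counts were 44 and 33. With a pseudocount of 0.1 in place of 1 they were 384 and 766.

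The time comparison sets cells at 6 h of GABA and taurine against cells at 0 h. Whether these cells were cultured before treatment is not given in the sources used here, and Foxl1 was below 0.3 FPKM in all 6 libraries. No library of the labels is an untreated 6 h control, so time and treatment cannot be separated here. After 6 h, 26 genes were higher and 34 lower among 10910 tested (limma, adjusted p under the threshold of 0.05). Of 21 interferon-stimulated genes tested, 6 rose. Oasl2, Irf7, Usp18, Isg15 and Stat2 of that list were among the 10 largest rises, with Ifit3 also past the threshold. Irf7 and Stat2, transcription factors of the interferon response, went from 15.2 ± 3.81 to 27.1 ± 4.39 FPKM (SD, n = 3) and from 12.7 ± 2.1 to 20.9 ± 1.31 FPKM. Usp18, the protease that removes Isg15 from proteins, went from 27.4 ± 6.57 to 47.5 ± 4.6 FPKM, and Isg15 from 17.9 ± 3.47 to 31.0 ± 5.12 FPKM. Oasl2 rose from 9.65 ± 1.95 to 17.6 ± 2.45 FPKM and Ifit3 from 20.4 ± 2.37 to 31.1 ± 1.63 FPKM. The adjusted p of these 6 genes lay between 0.0275 and 0.0408. Of the 21 members, 17 had positive and 4 negative log2 changes, among the latter Mx1 (-0.21) and Rsad2 (-0.27). Over all genes tested 6 passed, and 15 passed when adjusted over the list alone. The list's median log2 change was 0.40 (camera adjusted p = 5.6e-15; adjusted p = 0.144 with an estimated correlation), and fry gave an adjusted p of 0.0623. Leukocyte markers had a positive median in the same comparison, 0.65 over 5 members, which ran from 0.05 to 1.27 over all fits. Of all 26 higher genes, 17 had their highest 0 h value in replicate 3, 14 had their lowest 6 h value in replicate 1 and 11 had both, among them Isg15, Usp18, Irf7 and Stat2.

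The largest rise by the naming rule was that of Zbp1, a sensor of nucleic acids, from 5.83 ± 1.45 to 12.6 ± 2.39 FPKM (log2 change 1.00, SE 0.17, adjusted p = 0.0288). Ifi27l2a, Sp100 and Lgals3bp, outside the fixed list, also rose, Ifi27l2a from 62.7 ± 9.13 to 125.3 ± 27.7 FPKM, Sp100 from 5.88 ± 1.06 to 11.3 ± 2.25 FPKM and Lgals3bp from 54.5 ± 7.45 to 88.8 ± 13.6 FPKM. Chac1, an enzyme that breaks down glutathione and a target of the transcription factor ATF4, rose from 5.59 ± 1.35 to 11.9 ± 1.39 FPKM. The ATF4 and amino acid response list as a whole was not past the test (camera adjusted p = 0.666), and Psat1, an enzyme of serine synthesis, stood at 126 ± 3.27 and 108.3 ± 6.3 FPKM (adjusted p = 0.181).

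Of 16 NRF2 and antioxidant genes, 2 fell. Hmox1, the heme-degrading enzyme, dropped from 1076 ± 31.0 to 779.6 ± 42.2 FPKM (log2 change -0.47, SE 0.05, adjusted p = 0.00463), the smallest adjusted p of the comparison, shared with the pseudogene Apoo-ps. Hmox1 lies on chromosome 8 from 75093621 to 75100589. Gclm, a subunit of the enzyme that starts glutathione synthesis, dropped from 328.9 ± 5.51 to 279.4 ± 4.38 FPKM (adjusted p = 0.0478), a call kept in 6 of 17 fits, where that of Hmox1 was kept in 15. Txnrd1 (274.3 ± 8.2 and 237.7 ± 2.84 FPKM) and Pgd (247.7 ± 4.16 and 217.8 ± 4.09 FPKM) had adjusted p-values of 0.1 and 0.15. The median log2 change of the 16 members was -0.12, 15 of them were lower, 2 passed over all genes and 8 when adjusted over the list alone. The camera adjusted p was 7.63e-09, and the adjusted p with an estimated correlation was 0.144.

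Ier5l, an immediate early response gene relative, had the largest fall by the naming rule, from 24.8 ± 9.03 to 6.99 ± 3.66 FPKM (log2 change -1.71, SE 0.29, adjusted p = 0.0294). Ybx3, a nucleic acid binding protein, fell from 305.5 ± 92.7 to 114.7 ± 37.8 FPKM (log2 change -1.40, adjusted p = 0.0275). Smad4, the shared mediator of TGF-β and BMP signalling on chromosome 18 from 73639009 to 73703780, fell from 34.1 ± 7.17 to 14.7 ± 3.36 FPKM (log2 change -1.16, adjusted p = 0.0191). The kinase gene Akt1 fell from 158.2 ± 21.8 to 93.0 ± 17.5 FPKM, the G protein subunit gene Gna12 from 42.0 ± 7.15 to 20.5 ± 5.46 FPKM, and Ryk, a Wnt receptor, from 32.0 ± 8.28 to 16.0 ± 3.75 FPKM. Ppp2cb, a catalytic subunit of protein phosphatase 2A, fell from 34.6 ± 11.99 to 15.3 ± 4.24 FPKM. Sepn1, Marveld1 and Rcc2 completed the 10, with log2 changes of -0.88, -0.81 and -0.77. Of all 34 lower genes, 28 had their lowest 0 h value in replicate 3, and 27 had their highest 6 h value in replicate 3.

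**Figure D2:**
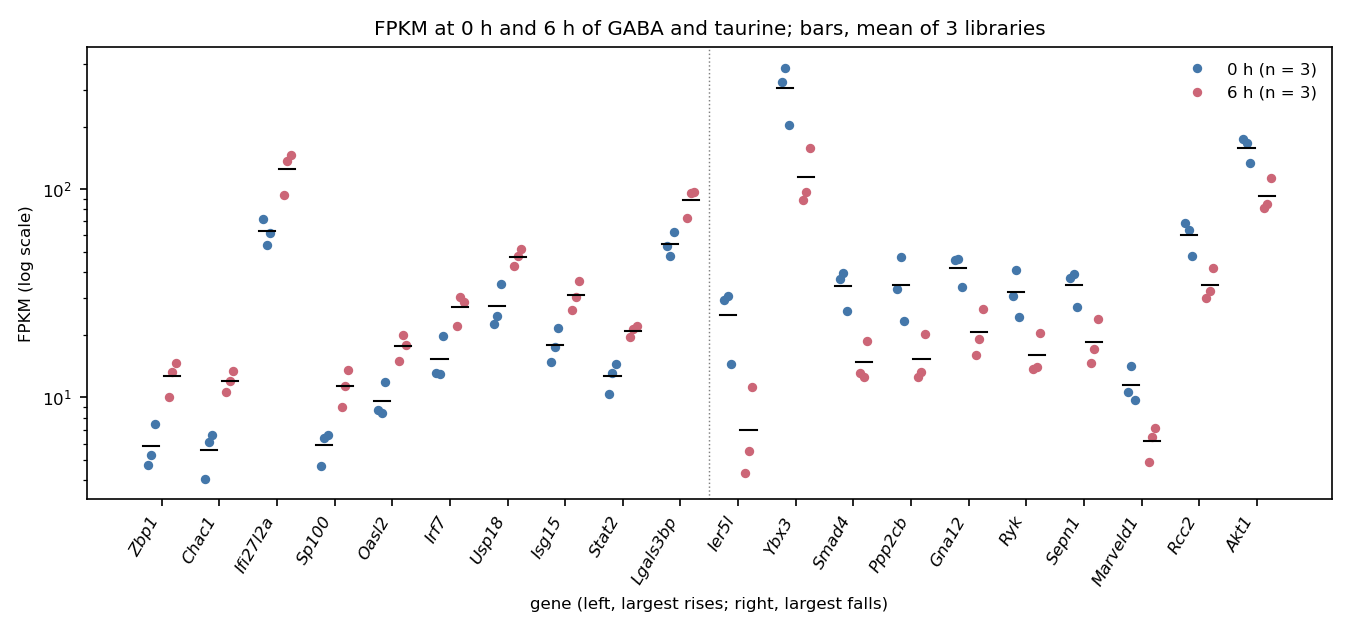
FPKM on a log axis (y axis) of the 10 largest rises and the 10 largest falls by the naming rule (x axis) in each library at 0 h (blue) and 6 h (red), 3 libraries each, with the mean as a black bar. The values of the 2 times do not overlap for any gene shown, which the naming rule requires. Means were, for example, 5.83 against 12.6 FPKM for Zbp1 and 305.5 against 114.7 FPKM for Ybx3.

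Matrix remodelling enzymes, chemokines, growth factors and collagens had positive medians, while few of their members passed singly. Matrix remodelling enzymes had a median log2 change of 0.13 (camera adjusted p = 0.00104; adjusted p = 0.144 with an estimated correlation), with 2 of 18 members past the test over all genes and 2 when adjusted over the list alone. The stromelysin Mmp3 rose from 548.4 ± 23.6 to 702.4 ± 10.02 FPKM (adjusted p = 0.0191) and Timp3, an inhibitor of such enzymes, from 64.2 ± 3.78 to 84.2 ± 5.93 FPKM (adjusted p = 0.0335), while Mmp9 and Mmp10 had adjusted p-values of 0.517 and 0.584. Chemokines had a median of 0.2 (camera adjusted p = 6.66e-05; adjusted p = 0.273 with an estimated correlation), which ran from 0.11 to 0.25 over all fits. Ccl11, which attracts eosinophils, rose from 29.5 ± 1.67 to 39.7 ± 1.26 FPKM (adjusted p = 0.0319), the only 1 of 13 members past the test over all genes, and 6 passed when adjusted over the list alone. Cxcl10 (79.1 ± 3.93 and 98.4 ± 6.44 FPKM), Ccl7 (1533 ± 66.9 and 1800 ± 65.9 FPKM) and Ccl2 (1752 ± 68.6 and 2050 ± 105 FPKM) were not past the test over all genes. Growth factors had a median of 0.10 (camera adjusted p = 0.00295; adjusted p = 0.144 with an estimated correlation), which ran from 0.05 to 0.16 with 1 library left out. Hgf, the ligand of the receptor Met, rose from 6.29 ± 0.689 to 10.2 ± 0.777 FPKM (adjusted p = 0.041), the only 1 of 21 members past the test over all genes and kept in 7 of 17 fits, where 4 passed when adjusted over the list alone. Btc stood at 5.71 ± 0.962 and 9.45 ± 0.918 FPKM (adjusted p = 0.0618). Ctgf and Vegfa had adjusted p-values of 0.125 and 0.296.

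Collagens and matrix proteins had a median log2 change of 0.08 (camera adjusted p = 0.000133; adjusted p = 0.273 with an estimated correlation), with 21 of 24 higher and a median from 0.06 to 0.13 with 1 library left out. No single member passed over all genes in limma, 4 had an unadjusted p under 0.05 and 3 passed when adjusted over the list alone. The smallest p-values were those of Dcn (295.8 ± 11.5 and 347.4 ± 15.6 FPKM), Lum, Col3a1 and Col14a1. Genes of Foxl1-positive subepithelial cells had a median of 0.19 (camera adjusted p = 0.000133; adjusted p = 0.144 with an estimated correlation), with 11 of 12 higher and a median from 0.13 to 0.24 with 1 library left out. In limma 0 of them passed over all genes and 3 when adjusted over the list alone, and 6 had an unadjusted p under 0.05. F3 stood at 412.8 ± 18.2 and 490.6 ± 28.9 FPKM, Pdgfra at 176.8 ± 22.1 and 217.9 ± 9.89 FPKM and Foxf1 at 64.1 ± 5.51 and 74.5 ± 3.38 FPKM, with Tgfbi next. Genes of CD81-positive fibroblasts, among them Rspo3, Ly6c1, Sfrp1 and Cd34, had a median of 0.14 (camera adjusted p = 0.00681; adjusted p = 0.273 with an estimated correlation). With 1 library left out that median ran from 0.09 to 0.19. In that list 0 of 16 members passed in limma over all genes and 0 when adjusted over the list alone, and 5 had an unadjusted p under 0.05. BMP ligands and antagonists, led by Bmp1, Fst, Bmp2 and Grem1, had a median of 0.15 (camera adjusted p = 0.0326; adjusted p = 0.273 with an estimated correlation). Of its 10 members 0 passed in limma over all genes, 0 when adjusted over the list alone and 2 at an unadjusted p under 0.05. The BMP list passed in 13 of 19 fits, and its median ran from 0.06 to 0.2 with 1 library left out.

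Camera with the preset correlation also placed cell cycle genes and ribosome biogenesis and MYC targets lower, with no single member past the test. Cell cycle genes had a median log2 change of -0.10 (camera adjusted p = 0.0106; adjusted p = 0.273 with an estimated correlation), with 16 of 20 lower. Cdc20, Mcm2, Rrm2 and Cdk1 had the smallest p, and Mcm2, part of the replicative helicase, stood at 41.1 ± 0.742 and 35.9 ± 0.626 FPKM. Ribosome biogenesis genes had a median of -0.06 (camera adjusted p = 0.0119; adjusted p = 0.333 with an estimated correlation), with 16 of 19 lower. Odc1, the rate-limiting enzyme of polyamine synthesis, stood at 399.2 ± 3.0 and 357.1 ± 19.7 FPKM, with Rrp9 and Ncl next, while Myc itself stood at 261 ± 11.9 and 282.8 ± 5.11 FPKM. Fry gave adjusted p-values of 0.0989 and 0.213. In these 2 lists 0 members passed over all genes and 0 when adjusted over the list alone, and 3 of 20 and 2 of 19 had an unadjusted p under 0.05 in limma.

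**Figure D3:**
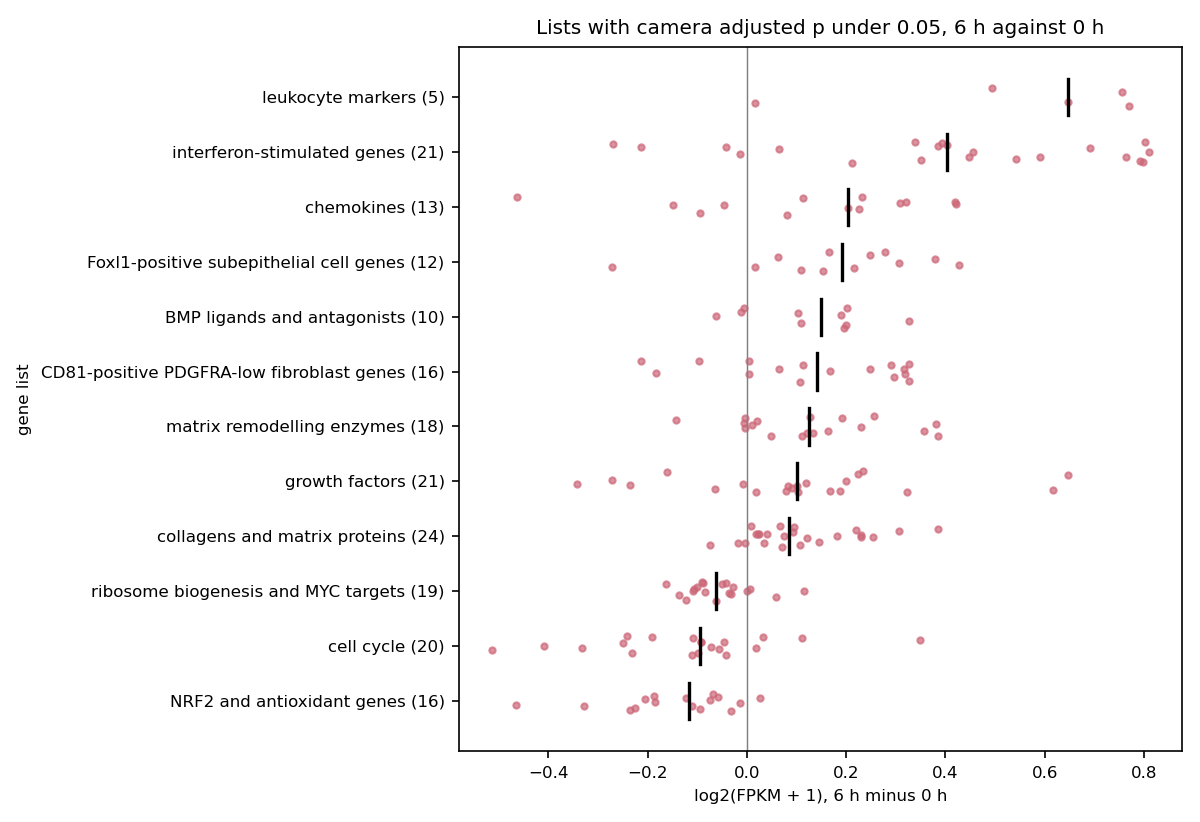
Change in log2(FPKM + 1) from 0 h to 6 h (x axis, mean of 3 libraries minus mean of 3) of each tested member (points) of the 12 lists past the camera test with a preset correlation (y axis, members in brackets), with list medians as black lines. Interferon-stimulated genes have a median of 0.40 and NRF2 and antioxidant genes a median of -0.12.

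Cxcl12 stood at 883.9 ± 28.9 FPKM at 0 h and 955.2 ± 12.6 FPKM at 6 h. The log2 change was 0.11 (SE 0.05) with an adjusted p of 0.459, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. Foxl1 was low, at 0.197 ± 0.0899 FPKM at 0 h and 0.2 ± 0.0229 FPKM at 6 h, below the filter of the test (exact two-sided permutation p = 1). Ackr3 (32.9 ± 1.1 and 33.03 ± 1.5 FPKM) and Pdpn (289.5 ± 12.4 and 293.1 ± 7.98 FPKM) differed by less than the spread between libraries. Ly6c1 stood at 9.59 ± 0.886 and 12.2 ± 0.154 FPKM (adjusted p = 0.314). Cxcr4, Epcam, Ptprc and Pecam1 had means under 0.3 FPKM at both times. Genes that handle the 2 added compounds did not pass the test. The GABA list had 3 of 27 members at or above 1 FPKM, with Gabrr2 at 1.86 ± 0.466 and 2.94 ± 0.885 FPKM and Abat at 7.55 ± 0.219 and 6.81 ± 0.63 FPKM (camera adjusted p = 0.524). The taurine list had 7 of 11, with the taurine transporter gene Slc6a6 at 22.8 ± 2.34 and 20.3 ± 1.47 FPKM and Ado at 21.5 ± 0.426 and 23.5 ± 0.962 FPKM (camera adjusted p = 0.565). The osmotic response list gave a camera adjusted p of 0.714. In 6 lists that did not pass, the median, the mean and the direction of the test differed in sign: ATF4 (median -0.01, mean 0.03, test down), osmotic response (-0.03, -0.004, up), immediate early genes (-0.007, 0.01, up), fatty acid oxidation (-0.03, 0.004, up), smooth muscle markers (0.04, -0.004, up) and hypoxia (0.002, -0.03, up).

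Few markers of cell types outside the gate reached the filter in these 6 libraries. Of 14 endothelial markers 5 did, among them Tek (7.92 ± 1.34 and 10.9 ± 1.44 FPKM, adjusted p = 0.319). The endothelial list had a median log2 change of 0.03 (camera adjusted p = 0.46), with 0 members past the test in limma over all genes, 1 when adjusted over the list alone and 2 at an unadjusted p under 0.05. Leukocyte markers had a median log2 change of 0.65 over 5 tested members (camera adjusted p = 0.0119; adjusted p = 0.378 with an estimated correlation), with 0 past the test in limma over all genes, 3 when adjusted over the list alone and 3 at an unadjusted p under 0.05. This list passed in 10 of 18 fits, and its median ran from 0.33 to 0.96 with 1 library left out and from 0.05 to 1.27 over all fits. Tyrobp stood at 0.473 ± 0.349 and 1.62 ± 1.12 FPKM, Cd74 at 1.72 ± 1.0 and 3.15 ± 0.899 FPKM and H2-Ab1 at 0.982 ± 0.731 and 2.33 ± 1.24 FPKM. Lyz2 stood at 2.75 ± 3.84 and 3.11 ± 2.42 FPKM, and its log2 change went from 0.49 to -0.16 without the 0 h replicate 1 library. Of the epithelial markers only Krt8 and Lgals4 reached the filter, and Krt8 rose from 0.396 ± 0.291 to 2.06 ± 0.285 FPKM (adjusted p = 0.0319).

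Every set test call at 6 h was lost in camera with an estimated correlation, where no list passed and 5 of 34 had an unadjusted p under 0.05. A higher correlation cannot account for every loss. The matrix remodelling, growth factor and Foxl1-positive lists had estimated correlations of -0.032, -0.021 and 0.005, below the preset 0.01. Their unadjusted camera p-values still rose, from 0.000184, 0.000608 and 1.74e-05 to 0.0155, 0.0199 and 0.0116. Fry called 3 lists, 2 of them also called by camera with the preset correlation, namely the antioxidant and the matrix remodelling lists, and the prostanoid list, where Ptgs1 stood at 15.6 ± 1.62 and 21.7 ± 0.201 FPKM. The gene counts were not firm. They were 0 higher and 0 lower in limma without the filter, with 631 and 691 genes at an unadjusted p under 0.05, and again 0 and 0 without the intensity trend, with 516 and 444 genes. Without replicates 1, 2 or 3 of 0 h, 3, 1 and 47 genes were higher and 3, 2 and 68 lower. Without replicates 1, 2 or 3 of 6 h, 2, 0 and 5 were higher and 2, 2 and 36 lower. The 3 values at 6 h all lay beyond the 3 at 0 h in 15.3% of tested genes, where chance gives 10% on average. Genes of the same libraries vary together and this share was not computed for other splits, so the 2 percentages do not form a test.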

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

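The GC corrections and the counts without small RNA genes were chosen after seeing the data. Genes higher at 6 h numbered 26 and genes lower 34. In limma the counts were 0 and 0 without the filter, where 631 and 691 genes had an unadjusted p under 0.05, and 0 and 0 without the intensity trend, where 516 and 444 had one. With a mean of at least 5 FPKM, 41 were higher and 44 lower, and with library quality weights 50 and 59. Leaving out 1 library gave 0 to 47 higher and 2 to 68 lower genes. The filter changes how many genes are tested, 17119 without it and 8009 at 5 FPKM, and leaving out a library removes a sample. For the other settings the cause was not tested. Median-ratio scaling (26 and 34), quantile normalisation (26 and 28), a pseudocount of 0.1 (27 and 38), transcript GC correction (29 and 36) and window GC correction (25 and 30) stayed within 1.5 times. No pairing by replicate number was visible: deviations of same-numbered libraries correlated at -0.044, 0.013 and -0.028, and not every library correlated best with its own number. The labels do not say whether the libraries were paired, and this check cannot settle it. With the replicate number as a block, 14 genes were higher and 9 lower. Of the 12 lists called at 6 h, 0 were called with an estimated correlation (5 of 34 at an unadjusted p under 0.05) and 3 with fry, 2 of them among the 12. Under the other settings 10 to 15 lists were called, and counting these 2 tools the lists that passed least often were leukocyte markers (10 of 18 fits), BMP ligands (13 of 19), ribosome biogenesis (13 of 19) and cell cycle (16 of 19). With 1 library left out the median of leukocyte markers ran from 0.3264 to 0.9577, of BMP ligands from 0.0605 to 0.1984, of growth factors from 0.0478 to 0.1611, of collagens from 0.0555 to 0.1289, of CD81-positive fibroblast genes from 0.0901 to 0.1947 and of Foxl1-positive cell genes from 0.1267 to 0.2414. Over all fits the median of leukocyte markers ran wider, from 0.0527 to 1.267, and that of chemokines ran from 0.1123 to 0.2498. Cxcl12 at 6 h kept its direction and stayed short of the threshold under every setting run, with log2 changes from 0.09 to 0.15 and adjusted p from 0.289 to 0.716. Of the named genes past the threshold that were followed through all settings (Krt8 and Nr4a1 were not), Hmox1 kept its call most often, in 15 of 17 fits (adjusted p from 0.00234 to 0.291), then Ifi27l2a in 13 and Mmp3 in 12. Ybx3, Smad4, Gna12 and Lgals3bp kept it in 11, Isg15, Usp18, Stat2, Oasl2, Ifit3, Zbp1, Sp100, Chac1, Akt1, Ier5l, Rcc2, Ryk and Sepn1 in 10, Irf7, Ccl11, Timp3, Ppp2cb and Marveld1 in 9, Hgf in 7 and Gclm in 6. Signs turned in 4 named genes that were never past the threshold: Ackr3 was -0.0072 with quality weights and ran from -0.0215 to 0.0412 with 1 library left out, Pdpn from -0.0042 to 0.053, Lyz2 from -0.1587 to 1.3149 and Foxl1, within its spread, from -0.0479 to 0.0603, and the cause was not tested. Genes below the filter of a setting gave no value there. Over all tested named genes, 855 values kept direction and side of the threshold, 187 no longer passed and 14 newly passed. In the genotype comparison Cxcl12 stayed lower under every setting. Genes at least 2-fold higher numbered 384 and lower 766 with a pseudocount of 0.1, which enlarges the ratios of low genes, and 44 and 33 at a mean of at least 10 FPKM, which removes low genes. Without the filter, after rescaling and without small RNA genes the counts stayed within 1.5 times. Of the 10 lists that stood apart, 7 did so at a mean of at least 10 FPKM, where the endothelial, osmotic and taurine lists lay at percentiles 29.5, 94.2 and 96.6. Without the filter the taurine list lost its place, at a median of 0.02 and percentile 49.1 where it had 0.29 and 98.5, and Wnt ligands stood apart at 2.45. With a pseudocount of 0.1 the osmotic list did not stand apart (96.8) and the ATF4 list did (97.8). The unknown read depth limits what can be said of genes near 1 FPKM.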

Other observations

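The tests of other splits of the libraries, of overall transcript GC content, of epithelial carry-over and of a lower share of sorted cells were written down only after their results had been seen. The 2 sets of libraries differed widely in level, although their labels name the same sorting gate. Whether the cells of the time comparison were cultured first and whether the sets were normalised together is not given in the sources used here. The cause of these differences, apart from those of the sex-linked genes below, stays open. Foxl1 was 10.2 to 11.6 FPKM in the genotype libraries and 0.11 to 0.289 FPKM in the 6 libraries of the time comparison. The matrix genes Col1a1 (1230 to 1387 FPKM), Col1a2 (1310 to 1466 FPKM) and Dcn (5741 to 6218 FPKM) were high in the genotype libraries, against 144.3 to 176.7, 74.7 to 85.4 and 288 to 363.9 FPKM in the 6 libraries. Gpx3 was 2929 to 2931 FPKM against 70.2 to 77.2 FPKM, and Fos 3478 to 3923 FPKM against 54.5 to 74.1 FPKM. In the other direction, Hmox1 was 733.1 to 1110 FPKM in the 6 libraries against 63.4 to 69.7 FPKM, Nqo1 79.6 to 101.7 against 5.92 to 6.5 FPKM, Ldha 1748 to 1886 against 346.5 to 440.7 FPKM and Ccl2 1676 to 2145 against 173.3 to 232.4 FPKM. Actb was similar, at 489.2 to 526 and 513.3 to 616.4 FPKM. Cxcl12 was 1298 FPKM in the control library and 860.4 to 969.4 FPKM in the 6. Leukocyte transcripts were present in the genotype libraries (Cd74 at 307.6 and 362 FPKM) and nearly absent from the 6 (0.887 to 3.96 FPKM). The Y-linked gene Ddx3y was 27.4 and 34.2 FPKM in the genotype libraries and at most 0.0117 FPKM in the 6, where Xist was 2.74 to 3.65 FPKM, against 0.181 and 0.188 FPKM. Eif2s3y, also Y-linked, was 24.4 and 21.3 FPKM in the genotype libraries and 0 in the 6. By these genes the genotype libraries came from male cells and the 6 from female cells. What sex adds to the other differences was not tested. Genes of this paragraph other than Cxcl12 and Foxl1 were chosen after their values were seen.

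A few more of the genes past the threshold at 6 h are given here as examples, and others past it are not named. Penk, the precursor of enkephalins, rose from 155.5 ± 9.95 to 196.6 ± 1.84 FPKM and Adcyap1r1, a receptor of the neuropeptide PACAP, from 49.4 ± 3.25 to 66.6 ± 2.74 FPKM. Ch25h, which makes 25-hydroxycholesterol and is interferon-inducible, rose from 22.3 ± 1.49 to 33.4 ± 3.01 FPKM, and the immediate early gene Nr4a1 from 49.4 ± 2.57 to 64.4 ± 4.51 FPKM. Mt1, a metallothionein, fell from 277.2 ± 17.4 to 222 ± 13.1 FPKM. Penk, Adcyap1r1, Ch25h and Mt1 were chosen after their values were seen.

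Epithelial markers of the fixed list were higher in the conditional knockout library. Epithelial cells that escaped the EpCAM gate are a candidate source: 17 of 17 measured markers were higher, and the most abundant, Car1 (614 FPKM), Guca2a (137.6 FPKM) and Krt8 (87.7 FPKM), were each more than 10 times their control values. All 17 were also detected in the control library, at lower levels, while Reg3b (23.6 to 9.57 FPKM) and Mptx1 (26.2 to 4.83 FPKM), genes of gut epithelium outside the list, were lower in the knockout library, which carry-over of the same mix of epithelial cells would not give. The number of reads behind these 2 genes is unknown, and the fall of Mptx1 may rest on few reads. A lower share of sorted cells that raised every other cell type alike is argued against by endothelial markers. Their upper quartile was 0.032, against a lower quartile of 1.28 for epithelial markers. The 3 endothelial markers with a mean of at least 10 FPKM had a median of 0.031. Leukocyte markers were higher in 13 of 16, but their upper quartile of 0.45 also lay below 1.28. A lower share of sorted cells with a different mix of other cell types was not tested and stays open. A change that follows from loss of Cxcl12 in the sorted cells stays open and cannot be told apart from a difference between 2 sorts, since there was 1 library per genotype.

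Clock output genes were lower in the conditional knockout library. This was noticed in Dbp and Tef and then tested on the others. The other 8 genes of the set, among them Hlf, Per3, Ciart, Nr1d1 and Bhlhe41, had a median log2 difference of -0.49, at percentile 0.05 of random lists matched on expression, although Per1 and Per2 were higher. The 4 antiphase genes (Arntl, Npas2, Clock and Nfil3) had a median of 0.31, at percentile 97.1, just short of the percentile set for the test. Tissue taken at different clock phases may account for this, but the labels used here give no collection time, and an effect of Cxcl12 loss cannot be told apart from it with 1 library per genotype.

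The genes past the threshold at 6 h varied together within each time: of 26 higher genes, 17 were highest at 0 h in replicate 3, 14 lowest at 6 h in replicate 1 and 11 both. Of 34 lower genes, 28 were lowest at 0 h in replicate 3 and 27 highest at 6 h in replicate 3, and 25 were both, against 13% of tested genes. A bias in overall GC content is argued against, since 32 of the 32 genes with a GC value still passed after correction for transcript GC, and a trend on local GC as the whole cause is argued against too, since 28 of 32 passed after correction for the most GC-rich window, with a median log2 change of -0.70 before and -0.67 after. The lower genes were nonetheless rich in such stretches: their median window GC was 80.8% against 71% for tested genes, at percentile 100 of random matched lists. Poor recovery of locally GC-rich cDNA that differs between libraries may therefore contribute, but over 10510 genes window GC correlated only at -0.05 and 0.03 (Spearman, across genes, which are not independent replicates) with the deviation of the replicate 3 libraries, so this and an effect of the treatment cannot be told apart.

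The 6 libraries of the time comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 26 higher and 34 lower genes, and the highest count of any other split in either direction was 1. It gave 12 lists, and the highest of the other splits gave 7. In each case 1 split, the real one, gave a result as large.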
